A study of Glycine max with 13 samples.

How the data were processed

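The study holds 13 samples, of which 12 are DAP-seq libraries of maize ARFs on soybean leaf DNA and 1 is a library of the GST-HALO tag alone. The 12 ARF samples each had 1 deposited peak list. The control library was not analysed here as a sample of its own. Per the submitters' processing notes, Trimmomatic 0.36 and Bowtie2 were used. The genome build, the settings of the peak caller and the filters are not given in the sources used here, and GEM, an event caller, is named only in the titles of the deposited lists.

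Each deposited list gives windows of 201 bp on 20 chromosomes with the event position at offset 100, which held for 100% of the events. The deposited signal value is the strength the authors gave each event; it ran from 17 to 20864 and was a whole number for 69.4% of the events, and no scaling is stated. The deposited −log10 p and −log10 q values were capped at 999, which 60 events reached, and the lowest −log10 q was 5. Lists were made per sample as far as the deposited files show. Strengths served to rank or filter events within a list, to infer control reads for the closing section and to name the strongest events. They have no stated common scale, so strengths of different lists are not comparable. The depth of each library is unknown, so a position without a peak may lie under the threshold of that list, and the Wilson intervals of shares cover counting error only.

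The groups came from the sample titles, and the clades from the published phylogeny of the maize ARF family, taken as background knowledge and not checked here against a source or sequences. Every clade result rests on this assignment. Event positions were written 1-based. Peaks of 2 lists were shared when their event positions lay within 100 bp, and the Jaccard index was the mean of both directions of sharing over the number of peaks in either list. Chance sharing came from 20 seeded circular shifts of one list along each chromosome per pair. For sites, events of all lists were chained together when consecutive positions lay within 100 bp. Clade differences were tested with two-sided exact permutation tests over all 924 splits of the 12 ARFs into 6 and 6, and adjusted with the Benjamini-Hochberg method over the 2 tests. Clade-restricted sites had peaks of at least 4 ARFs of one clade and 0 of the other, and were counted again in 100 splits drawn with a fixed seed, the real one included. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

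The code was tested on simulated data of 20000 sites in 12 libraries. It recovered 1917 of 1917 planted clade A-restricted sites and 2092 of 2092 planted clade B-restricted sites. The planted sites lay much farther apart than the merging distance of 100 bp, so this checks the counting and not the merging of close events. Separately, 4% of 200 sets of 12 random values gave p at or under 0.05 in the permutation test of clade means. These sets held no sites, and an exact test keeps this level by design. The permutation test of sharing had no such check.

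The rule for named sites, the tests in the report and the settings listed next were fixed before the data were examined. The rule took the 10 sites with peaks of the most ARFs and, for each clade, the 5 restricted sites with the most ARFs, with ties broken by the mean percentile of strength. Other settings were distances of 50 and 200 bp, only events at or above the median −log10 q of their list, the strongest 1106 events of each list, the overlap coefficient, the phi coefficient, restricted sites of at least 5 ARFs of one clade and at most 1 of the other, and leaving out each ARF. A setting without events that imply control reads, all settings tried for the sites with all 12 ARFs, and the measures of the closing section were chosen after seeing the data. Tests of genomic location, of motif content, of the spacing of TGTC pairs and of gene lists near peaks were planned on the condition that the build matched a reference. They were not run, because no build is named and no genome sequence was used here. The gene table at hand is of assembly Glycine_max_v4.0, and its coordinates were not used.

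For the closing section, control reads were inferred from the deposited strength and p of each event, as the number of opposing reads that gives that p in a binomial test at even odds. This formula is an inference from the values, since the sources used here do not give it. Events with −log10 p above 290, 67 in all, could not be read. Among events with whole strengths, 48.7% to 59.3% per list implied no opposing reads, and of the values of 1.5 or more, 93.2% to 98.7% per list lay within 0.05 of a whole number. Over all events with whole strengths this share was 82.1% for ARF29, 82.9% for ARF4, 87.4% for ARF27 and 98.0% to 99.2% for the other lists, so many small values of those 3 lists are not whole reads. These values rose in steps, and the step of a list, in library reads per control read, was fitted by maximum likelihood with geometrically distributed control reads and evenly spread strays. It was the third way of fitting tried. The first scored the share of values on the steps minus the share chance gives and placed ARF10 at 1.99, against its own commonest values of 2, 4 and 5. The second divided that excess by the room left above chance. On 12 simulated steps the likelihood came within 5% for 12, the first scoring for 8 and the second for 2, and the likelihood was chosen on this basis. The simulated values followed the model that the likelihood assumes, which favoured it in advance. The simulation therefore does not show how well the likelihood fits the deposited lists. To compare lists, the opposing reads of an event were divided by the step of its list and rounded down after a small allowance. A median of 84.3% of shared events per pair of lists then gave the same number of control reads, against 21.5% after permutation (66 pairs, events within 5 bp and of strength 50 or more).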

Results

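DNA affinity purification sequencing (DAP-seq), in which a tagged transcription factor made outside the cell is incubated with naked, fragmented genomic DNA and the bound fragments are sequenced, was run with 12 maize auxin response factors (ARFs) on genomic DNA from soybean leaf. ARFs are the DNA-binding proteins through which the hormone auxin changes transcription. Each ARF had 1 library and 1 peak list, so no ARF has a replicate check. A library of the tag without an ARF (GST-HALO) was part of the study and was not analysed here. The 12 proteins fall into 2 clades of the published maize ARF phylogeny, which the sample labels do not give and which was taken as background knowledge, without a check against protein sequences: clade A (ARF4, ARF16, ARF18, ARF27, ARF29 and ARF34), whose members are generally described as activators, and clade B (ARF7, ARF10, ARF14, ARF25, ARF36 and ARF39), generally described as repressors. The 6 proteins of a clade were the units of every clade comparison, and the p-values measure the spread between proteins that each rest on a single library. The lists give no read totals, so the depth of each library is unknown and the length of a list can depend on it.

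The first comparison asked how many places in the soybean genome each ARF occupied. ARF34 of clade A had the most peaks, 35715, and ARF18 of the same clade the fewest, 1106, a 32.3-fold range. In clade A, ARF4 had 19478 peaks, ARF16 had 16964, ARF27 had 10248 and ARF29 had 5395. In clade B, ARF36 had 22516 peaks, ARF7 had 20802, ARF25 had 19058, ARF10 had 12286, ARF14 had 9542 and ARF39 had 4210. The 12 lists held 177320 peaks in all, and every list had peaks on all 20 chromosomes. The clades did not differ in mean log10 number of peaks beyond the spread between proteins: 3.98 ± 0.53 (SD, n = 6) in clade A and 4.11 ± 0.28 (SD, n = 6) in clade B (two-sided exact permutation test over 924 splits, p = 0.63, Benjamini-Hochberg adjusted over 2 clade tests 0.63). Without ARF18 the difference, A minus B, turned from -0.13 to 0.056.

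**Figure D1:**
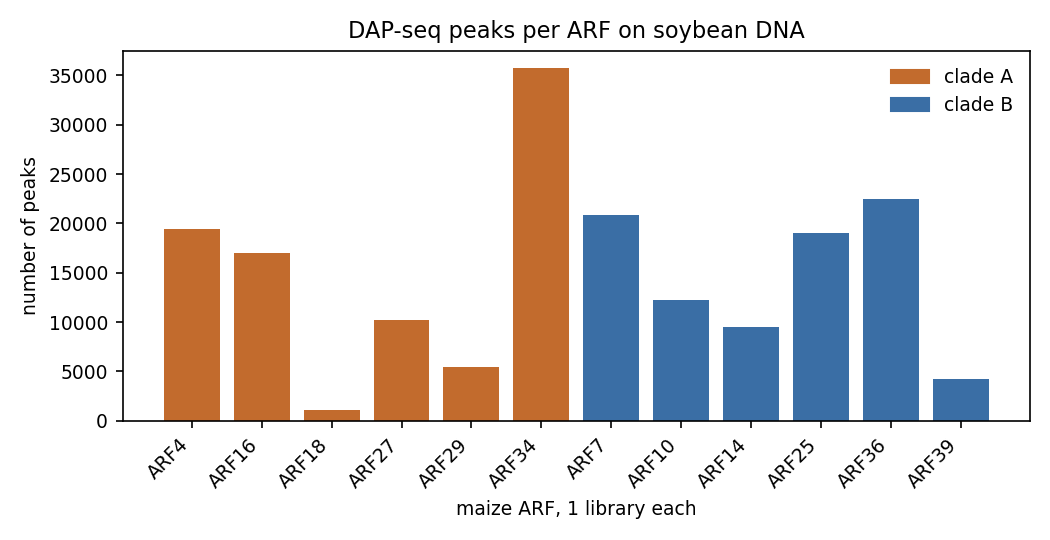
Number of DAP-seq peaks in the single library of each of the 12 maize ARFs on soybean DNA, clade A in orange and clade B in blue. The bars run from 1106 peaks for ARF18 to 35715 for ARF34, and both clades hold long and short lists.

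The second comparison asked how far the 12 proteins occupied the same positions. Peaks were counted as shared when their event positions, the single bases at which the authors placed the binding event, lay within 100 bp. The closest pair was ARF10 and ARF25 of clade B, with a Jaccard index (shared peaks over all peaks of both lists) of 0.445, and 77.7% of the ARF10 peaks lay at an ARF25 peak (Wilson 95% interval 76.9% to 78.4%). In clade A the closest pair was ARF16 and ARF34, with an index of 0.429, and 92.5% of the ARF16 peaks lay at an ARF34 peak. Sharing exceeded chance in all 66 pairs: each index was higher than in every one of 20 circular shifts of one list along the chromosomes, by 29.2-fold or more over the mean of the shifts, and the highest index of any shifted list was 0.0033. The shifts place peaks anywhere along a chromosome, so they do not allow for regions that favour peaks of any ARF. The mean index over the 66 pairs was 0.166.

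Most peaks of the shortest list of each clade lay at peaks of the other lists of that clade. Of the 1106 ARF18 peaks, 98.0% lay at an ARF16 peak, 96.0% at an ARF34 peak, 90.3% at an ARF27 peak, 87.4% at an ARF4 peak and 70.2% at an ARF29 peak, against 35.1% to 53.7% at the peaks of the clade B proteins. Of the 4210 ARF39 peaks, 93.1% lay at an ARF36 peak, 87.4% at an ARF25 peak, 84.2% at an ARF14 peak, 75.4% at an ARF7 peak and 67.0% at an ARF10 peak, against 28.1% to 42.4% at the peaks of clade A proteins other than ARF18. The share of sites found for a single ARF ranged from 0.37% for ARF18 to 38.3% for ARF34. It was 32.3% for ARF7, 24.3% for ARF4, 20.3% for ARF36 and 16.4% for ARF25, and between 1.19% (ARF39) and 6.39% (ARF10) for the other lists. It did not simply follow the length of the list: ARF16, with 16964 peaks, had 3.66%.

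Proteins of one clade shared more positions than proteins of different clades. The mean Jaccard index was 0.205 ± 0.119 (SD, 15 pairs) within clade A, 0.302 ± 0.090 (SD, 15 pairs) within clade B and 0.093 ± 0.035 (SD, 36 pairs) between the clades. Over same-clade pairs it was 0.253, which is 2.72 times the mean of different-clade pairs (two-sided exact permutation test over 924 splits of the 12 proteins, p = 0.0022, the smallest value this design can give, adjusted over 2 clade tests 0.0043). The best partner of each of the 12 ARFs was a protein of its own clade, and the mean index with the own clade was above that with the other clade for 12 of 12. For single pairs the separation was complete in clade B and not in clade A: every same-clade index was above every other-clade index for all 6 clade B proteins and for 0 of the 6 clade A proteins. ARF29, for example, had an index of 0.113 with ARF34 of its own clade and of 0.140 with ARF39 of clade B, and the lowest same-clade index of ARF4, ARF16, ARF27 and ARF34 was the one with the short ARF18 list. ARF18 had the lowest mean index with its own clade, 0.077, against 0.040 with clade B. A list of 1106 peaks cannot have a high index with a long list, and with the 1106 strongest peaks of every list the mean of ARF18 with its own clade was 0.308.

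**Figure D2:**
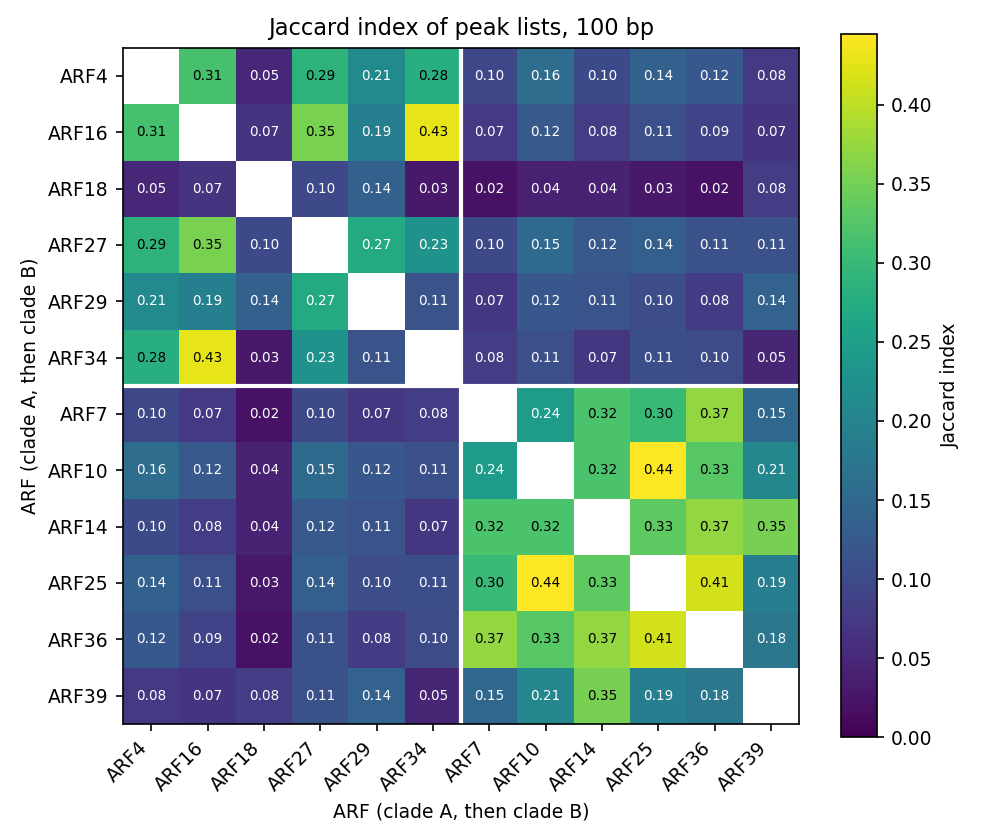
Jaccard index of each pair of the 12 ARFs (colour and printed value, 1 library per ARF, peaks shared within 100 bp), with clade A before clade B on both axes and white lines between the clades. The blocks within clade A (mean 0.205) and within clade B (mean 0.302) stand above the blocks between the clades (mean 0.093).

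Merging event positions closer than 100 bp gave 71895 sites. Of these, 34345 (47.8%) carried a peak of a single ARF, 5908 (8.22%) carried peaks of at least 6 ARFs and 240 (0.33%) carried peaks of all 12. Among the 37550 sites with peaks of at least 2 ARFs, 14446 (38.5%) had clade A proteins only, 12731 (33.9%) had clade B proteins only and 10373 (27.6%) had both.

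The third comparison asked which sites were restricted to one clade, counted as peaks of at least 4 of the 6 proteins of that clade and of none of the other. There were 2851 sites restricted to clade A and 4173 restricted to clade B, 7024 in all. Clade A-restricted sites made up 47.3% of the 6030 sites with at least 4 clade A proteins (Wilson 95% interval 46.0% to 48.5%), and clade B-restricted sites 50.7% of the 8225 sites with at least 4 clade B proteins (49.7% to 51.8%). All 6 clade A proteins without any of clade B were found at 150 sites, and all 6 clade B proteins without any of clade A at 712. Leaving aside the short ARF18 list, the other 5 clade A proteins without any of clade B were found at 867. At 1652 sites at least 4 proteins of each clade had a peak. ARF34 had a peak at 99.4% of the clade A-restricted sites, ARF16 at 97.4% and ARF18 at 12.5%. ARF36 had a peak at 99.1% of the clade B-restricted sites, ARF25 at 95.3% and ARF39 at 35.5%. With 1 ARF left out, at least 4 of the 5 left in its clade were required, a stricter rule that alone removes sites of exactly 4 ARFs, such as 1851 of the 2851 clade A-restricted sites, when the ARF left out was among them. Under it the clade A count was 1019 without ARF34, 1079 without ARF16, 1130 without ARF4 and 1314 without ARF27, and the clade B count was 2155 without ARF36, 2302 without ARF25 and 2619 without ARF7.

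**Figure D3:**
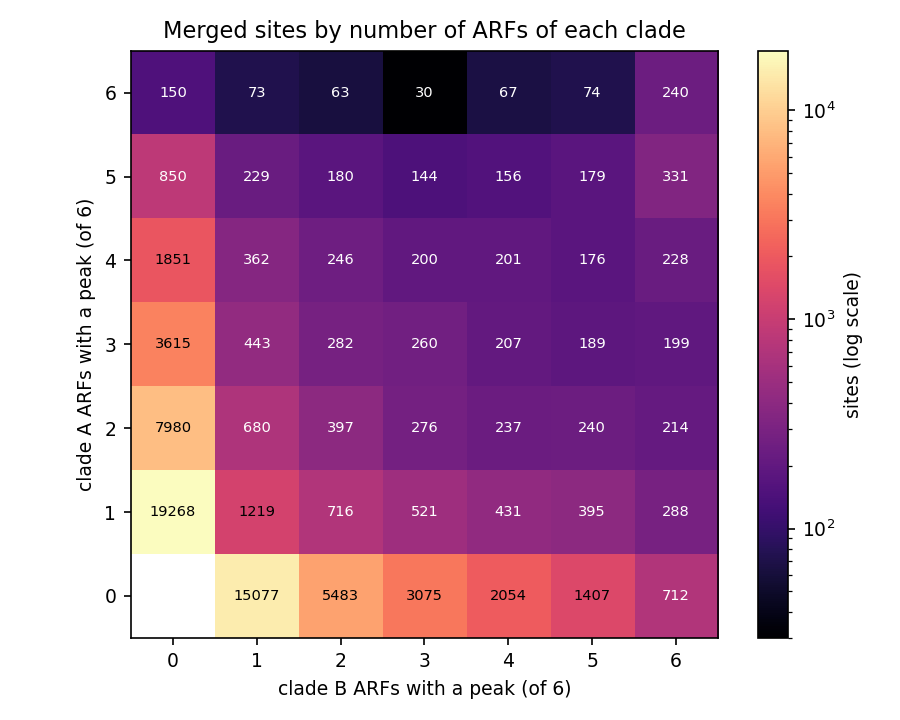
Number of merged sites (printed, colour on a log scale) by how many of the 6 clade B ARFs (x axis) and of the 6 clade A ARFs (y axis) had a peak there. The bottom row and the left column hold the sites of a single clade, such as the 712 sites with all 6 clade B ARFs and no clade A ARF, and the top right corner holds the 240 sites with all 12.

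Named sites are given by position on the chromosomes of the files, whose genome build is not given in the sources used here, so the genes at these positions were not analysed here. Strength is the authors' own value for an event, and its rank within a list is given as a percentile. The 10 sites with peaks of all 12 ARFs and the highest mean percentile had mean percentiles from 99.2 to 99.8, and each implied control reads, by the inference described with the processing, in every list whose p could be read. The same held for 8 of the 10 named clade-restricted sites. Control reads scaled to the library had medians of 3.73% to 26.2% of the strength at the former and of 0% to 6.93% at the latter. The first spanned event positions 3960034 to 3960205 of chromosome 8, with a mean percentile of 99.8 ± 0.35 (SD over 12 ARFs) and, for the strongest event of each ARF there, strengths from 263.4 to 1787. The next were at 30944492 to 30944521 of chromosome 14 (256 to 1039 by the same measure) and 24156319 to 24156349 of chromosome 8 (237 to 1075). The others lay on chromosome 7 at 16936350 to 16936365 and 2268491 to 2268498, on chromosome 15 at 7722548 to 7722558 and 4747777 to 4747780, on chromosome 16 at 6410878 to 6410885, on chromosome 20 at 42542228 to 42542276 and on chromosome 5 at 36748728 to 36748739.

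The leading clade A-restricted sites carried peaks of all 6 clade A proteins. They lay at 36174805 to 36174841 of chromosome 1 (mean percentile 97.1 ± 2.5, SD over 6 ARFs), 7323022 to 7323038 of chromosome 5 (95.4 ± 4.8), 33837029 to 33837051 of chromosome 1 (94.4 ± 6.8), 33996345 to 33996358 of chromosome 20 (94.4 ± 7.0) and 36567524 to 36567562 of chromosome 5 (93.5 ± 6.2). The leading clade B-restricted sites carried peaks of all 6 clade B proteins. They lay at 23660738 to 23660754 of chromosome 17 (99.7 ± 0.65, SD over 6 ARFs), 38457586 to 38457697 of chromosome 12 (99.5 ± 0.55), 23692733 to 23692862 of chromosome 17 (99.4 ± 0.82), 22941022 to 22941043 of chromosome 16 (99.4 ± 0.59) and 8717418 to 8717431 of chromosome 19 (98.8 ± 0.76). Strength was lowest at sites of 1 ARF and highest at sites of all 12, without a steady rise between: the median over sites of the mean percentile was 31.5 at sites of 1 ARF, 63.1 at sites of 6, 58.9 at sites of 7, 60.2 at clade A-restricted sites, 59.3 at clade B-restricted sites, 71.7 at sites with at least 4 ARFs of each clade and 87.4 at sites with all 12.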

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

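The alternatives were planned before the data were examined, except the removal of events that imply control reads and the alternatives for the sites with all 12 ARFs, which were chosen after seeing the data. The same-clade excess in the Jaccard index (0.160) stayed positive at an exact permutation p of 0.0022 under 19 of 19 alternatives, from 0.142 without ARF14 to 0.185 without ARF18 when 1 ARF was left out. The phi coefficient, the correlation of the presence of 2 ARFs over the merged sites, averaged 0.334 in same-clade pairs and 0.0054 in different-clade pairs. It leaves out all positions without a peak of any ARF, which lowers it. The mean index over all pairs (0.166) ran from 0.146 at 50 bp to 0.186 with 1106 events per list under 5 alternatives. All 5 lay within 1 SD between single pairs (0.114), a margin too wide to test a mean. The clade difference in log10 peaks did not pass the threshold under any of 14 alternatives. Leaving out 1 ARF gave -0.25 (without ARF34) to 0.056 (without ARF18, where the direction turned). Counts of sites fell with fewer events per list or stricter sites, and the cause was not tested. With events at or above the median −log10 q of their list there were 1475 clade A-restricted and 2238 clade B-restricted sites, 3713 in all, and 109 sites with all 12 ARFs. With 1106 events per list these were 303, 368, 671 and 38, and without events that imply control reads 1518, 2391, 3909 and 99. With at least 5 ARFs of one clade and at most 1 of the other, there were 1302 clade A-restricted sites and 4104 in all. Leaving out 1 ARF, with at least 4 of the 5 left then required, gave 1019 to 3112 clade A-restricted sites, 2155 to 4691 clade B-restricted sites and 5119 to 6954 in all. The clade A count moved by over 1.5 times without ARF4 (1130), ARF16 (1079), ARF27 (1314) or ARF34 (1019), and the clade B count without ARF7 (2619), ARF25 (2302) or ARF36 (2155). The planned tests of genomic location, motif content, spacing of TGTC pairs and gene lists, with their alternatives, were not run. Unknown depth limits every statement that a site lacks an ARF.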

Other observations

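The tests of read depth and of control reads were chosen only after the results they bear on, or closely related values, had been seen. The drawn splits were fixed beforehand, but how to read them was written down after their result. The tests that weigh ARF18 and the distances between events were written down before their results were seen, though the difference in distance itself had been seen. None of 16 groups of 6 ARFs, over 8 measures per library, had an end value whose gap to the next exceeded 0.625 of the range. The largest ratios were those of ARF18, 0.568 for its mean index with the other clade and 0.558 with its own. With 6 values such a rule detects only extreme gaps, so an unusual library is not excluded.

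Events of one clade coincided more closely than events of different clades. The median distance between shared events averaged 9.2 bp over same-clade pairs and 13.6 bp over different-clade pairs, and the ranks of their strengths were also more alike, with a mean Spearman rho across events of 0.53 against 0.36 (both exact permutation p = 0.0022, adjusted over 7 tests 0.0030; events are not independent replicates). Of the sites with at least 4 ARFs of each clade, 34.3% lay in the middle of the chromosomes, between 25% and 75% of the span covered by events (Wilson 95% interval 32.1% to 36.6%). The sites with all 12 ARFs are part of these, and 39.6% of them lay there (33.6% to 45.9%). The share in the middle was 46.4% for clade A-restricted sites (44.6% to 48.2%) and 50.3% for clade B-restricted sites (48.8% to 51.8%). For sites of 1 ARF it was 48.2% (47.6% to 48.7%), between the shares of the clade-restricted sites. These differences were not tested. Per list, the share of events in the middle was 43.5% ± 2.7 (SD, n = 6) in clade A and 46.2% ± 2.7 (SD, n = 6) in clade B, which did not differ by the exact permutation test (p = 0.12, adjusted 0.12). Events with another event of the same list within 500 bp made up 5.93% (ARF29) to 20.4% (ARF16) of the clade A lists. In the clade B lists they made up 6.37% (ARF39) to 9.72% (ARF7). Over random placement this was 4.79-fold (ARF34) to 62.9-fold (ARF18) in clade A and 3.97-fold (ARF36) to 13.4-fold (ARF39) in clade B. The share under random placement was larger for longer lists, from 0.13% for ARF18 to 3.62% for ARF34. The folds are therefore not comparable between lists of different length. The clade means of the observed share, 12.5% ± 5.5 and 8.3% ± 1.3 (SD, n = 6 each), did not differ by the exact permutation test (p = 0.11, adjusted 0.12).

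A smaller distance could arise if stronger events, placed more precisely, were more often shared within a clade. With events at or above the 75th percentile of both lists, same-clade pairs were still closer, by a difference of -2.3 bp (exact permutation p = 0.0022), which argues against this as the whole cause. With only events at the 1652 sites with at least 4 ARFs of each clade, the difference was -3.7 bp (exact permutation p = 0.0022). This argues against sites of a single clade as the whole cause. Each pair was still compared only where both lists had a peak, at 363 to 1726 shared events. The sites therefore differed between pairs, and a remaining difference in the sites compared is not excluded. A candidate explanation that stays open is that the clades contact different bases of one site. It was not tested, since no sequence was used here.

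The 32.3-fold range of list lengths might reflect read depth. The inferred step, in library reads per control read, ran from 1.45 (ARF18) to 4.68 (ARF29). It compares background depth between lists only if all were called against the same control, which the sources used here do not state. The number of peaks need not rise in proportion to depth. Over 12 ARFs log10 peaks did not follow the step (Pearson r = 0.07, permutation p = 0.84; Spearman rho = -0.16, permutation p = 0.61; r = 0.16 without ARF4 and ARF29). With the 2 other ways of fitting the step, rho was -0.09 (permutation p = 0.78) and 0.03 (permutation p = 0.92), and the lowest adjusted p over these 4 tests was 0.92. Lists within 15% of each other in step differed up to 11.1-fold in length (ARF10 against ARF18), and up to 8.48-fold and 20.4-fold with the first and second ways of fitting. The second way recovered only 2 of 12 simulated steps, so its 20.4-fold and its rho of 0.03 carry little weight. By the first way ARF10 (1.99) and ARF18 (1.49) were not within 15%, so equal depth is not shown for ARF18. ARF34 and ARF39, 8.48-fold apart in length, were within 15% by every way of fitting. If all lists had the same control, this argues against background depth as the whole cause of the range. ARF18 may show a lower yield of the same binding: the events of the other 5 clade A lists that it shares had median strength percentiles of 85.3 or more in each list, as that explanation needs. Sites of all 12 ARFs were also stronger than sites of 1 ARF (87.4 against 31.5), and no other short list was compared. The high percentiles therefore do not tell a lower yield from another cause of a short list. ARF18 shared 23.9% to 56.6% of their events at or above the 90th percentile, against 0.94% to 9.91% of the rest. The length of the ARF18 list limits the former share in the longer lists, but not in those of ARF27 and ARF29. There the share was 50.7% and 56.6%, so many of their strongest events had no ARF18 peak, and a lower yield is not established. Protein amount and affinity were not tested and stay open.

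The 240 sites with all 12 ARFs could be places where reads also pile up in the control. At 95 of them (39.6%) no list that could be read implied control reads. The median strength over the events of a site, in steps of the lists, was worth 12.9 or more control reads at each of these sites. Events of single lists can be worth fewer. By this inference, reads did not pile up in the control at these 95 sites. The share does not decide for the rest, because passing the caller's threshold would itself favour events with few control reads. None were implied either at 61 of the 240 strength-matched sites of 6 to 11 ARFs. At sites of 1 to 11 ARFs the share without any was 38.0% to 52.1%. For the sites as a whole, pile-up in the control cannot be told apart. The median of control reads was 1, a difference of 0 from the strength-matched sites (bootstrap 95% interval -1 to 0). From all 5668 sites of 6 to 11 ARFs the difference was 1 (0 to 1). Strength itself would hold any background, so the matched comparison does not decide. A median of 10 or more control reads was found at 11 of the 240 sites (4.58%), at 18 of the 240 matched sites and at 0.55% of all sites of 6 to 11 ARFs. Scaled control reads had medians of 3.73% to 26.2% of the strength at the 10 named sites with all 12 ARFs and of 0% to 6.93% at the 10 named clade-restricted sites, and the control library itself was not analysed here.

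Of 100 drawn splits of the 12 ARFs, only the real one reached the count of 7024 clade-restricted sites. The highest of the other drawn splits gave 3274. This is a share of 1 in 100, the smallest that 100 splits can give. Splits that were not drawn can give more than 3274. Exchanging ARF18 and ARF39, for example, keeps every restricted site without them. ARF18 had a peak at only 12.5% of the clade A-restricted sites and ARF39 at 35.5% of the clade B-restricted ones. The split result rests on the same lists as the clade difference in sharing and is not separate evidence.

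The events with the highest listed strengths lay at 3 sites, with the strongest event of each ARF given here and no common scale between lists. At 32738788 to 32738801 of chromosome 20, 9 ARFs had peaks with strengths from 1069.4 to 20864, and the implied control reads, scaled to the library, had a median of 33.7% of the strength in the 3 lists that could be read. On chromosome 12, 11 ARFs had peaks at 40628933 to 40628967 with strengths from 1956.3 to 10507 and scaled control reads of a median 38.2% of the strength in the 2 lists that could be read. On the same chromosome, 5 clade B ARFs also had peaks at 40632130 to 40632138 with strengths from 7887.2 to 17268.1, where no list could be read. The lists that could not be read were those with the highest −log10 p there. The medians therefore describe the other lists only and may be higher than in the lists left out. These sites were chosen after their values were seen.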
